A study of Candidozyma auris with 4 samples.

How the data were processed

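RNA was measured in 4 libraries of Candida auris isolate AR0390, 1 each for the control, lopinavir, itraconazole and the combination. Per the labels' protocols, RNA was selected by poly(A) tail and sequenced as TruSeq libraries on a NovaSeq instrument. The deposited values were whole counts per gene in 1 table with 4 count columns, and the submitters' processing notes name fastp, HISAT2 2.1, featureCounts 2.1 and edgeR 3.16.5 without linking each to a column. The genome build, the strand setting and the treatment of reads with several mapping positions were not given in the sources used here. The gene length in the same table, deposited in bases, was used only as a covariate and to describe positions. The table held 5714 genes, of which 140 had no read in any library and 3 lacked the annotation columns, and all 4 count columns were assigned to a group (0 columns were left unmapped).

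Gene IDs were joined to the reference table of the assembly ASM301371v2, which named locus tags for 5342 of them and left 372 unmatched; 2235 of the matched genes had a symbol. Reads on unmatched genes made up 4.09% of the control library, 4.39% of the lopinavir library, 4.47% of the itraconazole library and 4.62% of the combination library. Positions printed in the report are those of the deposited table. GC content and lists that need protein signatures were left out, since a genome sequence and signatures were not used here.

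The totals were 19603225 counts in the control, 20189335 with lopinavir, 22669738 with itraconazole and 21742656 with the combination, with medians of 1474, 1524, 1702.5 and 1662 counts per gene. A count of 3 corresponded to 0.155, 0.148, 0.132 and 0.137 CPM, which sets the floor of detection. Genes with at least 50 reads numbered 5312, 5317, 5329 and 5324, and the 20 most abundant genes took 11.6%, 11.9%, 11.3% and 10.9% of the counts.

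Libraries were normalised by the trimmed mean of M values in edgeR 4.0.16 under R 4.3.3, with factors of 0.985, 1.002, 1.004 and 1.009. Log2 ratios were taken after a prior count of 2 was added in proportion to library size. With 1 library per group no spread within a group could be estimated. An additive model of the 2 drugs, which leaves 1 residual degree of freedom, was not fitted, because it takes as noise the departure from additivity that was to be described; size was judged instead. A gene counted as higher or lower when the ratio was at least 2-fold and at least 1 of the 2 libraries held 50 reads; for the departure from additivity the limit was 1 log2 unit with 50 reads in at least 1 of the 4 libraries. Intervals of ratios are exact conditional binomial 95% intervals on the counts, and they leave out the variation between cultures. The departure from additivity is the log2 ratio of the combination to the control minus the sum of the log2 ratios of each drug to the control.

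The comparisons, the gene lists, the size rule and most alternatives were fixed before the data were examined. Genes are named in the report when they were fixed in advance (UPC2, CDR1, ERG11, ERG3 and MDR1), when they were among the 12 highest or 12 lowest named genes of a comparison with at least 100 reads in 1 library, or when a list brought them in: up to 6 members past 2-fold for ergosterol, hexose transport, ABC and major facilitator genes, and the 2 highest and 2 lowest members for every other list; any other gene is marked as chosen after its values were seen. Of 28 lists fixed by symbol, 23 had at least 5 measured members. Aspartyl proteases and cytochrome P450 genes had fewer and are given gene by gene, and protein kinases, mitochondrial carriers and the mitochondrial genome had no usable symbols. Each list's median was placed among 10000 random lists of equal size drawn from the same 20 bins of mean expression, as a description of these libraries. Symbols were those of the reference table, in which TAC1 and FKS1 were absent.

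Overlaps of gene sets were set against the number given by independent lists and against 100 simulations of unchanged libraries, with Poisson noise alone and with added library noise of 0.0911 log2 units. This noise came from the scaled median absolute deviation (0.129) of the log2 ratio of the combination to itraconazole, the pair that differed least. It was equal for all genes and does not measure variation between cultures. The procedure was tested on simulated data for all 5714 genes, 200 of them altered by known amounts, before it was run on the real counts. Alternatives were DESeq2 1.42.0 size factors, library totals, no minimum or a minimum of 200 reads, prior counts of 0.5 and 10, removal of the 20 most abundant genes, a 3-fold rule, subtraction of a lowess trend of the ratios on gene length, thinning of every library to the smallest total and, added after the files were seen, random lists matched on gene length as well. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.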

Results

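Poly(A)-selected RNA of the yeast Candida auris, isolate AR0390, was sequenced after cultures in exponential growth had received lopinavir at 10 µg/ml, itraconazole at 1 µg/ml, both drugs at these doses, or neither. Lopinavir is an HIV protease inhibitor, and itraconazole is an azole antifungal that inhibits the sterol demethylase encoded by ERG11. The study concerned the joint action of the 2 drugs, so the design gave the comparisons of each drug and of the combination with the control, of the combination with each single drug, and of the combination with the sum of the single-drug differences. The control library carried the label of no treatment, while the treatment protocol named 1% DMSO for this arm. The solvent of the drug cultures was not given in the sources used here, so a solvent difference is not excluded from any ratio to the control. Each of the 4 groups held 1 library, so no difference below has a replicate check and no p-value is given. The libraries held 19603225 counted fragments or reads in the control, 20189335 with lopinavir, 22669738 with itraconazole and 21742656 with the combination, over 5714 genes. Ratios compare 2 libraries, and their 95% intervals cover counting error only. A gene was counted as higher or lower when its normalised count was at least 2-fold apart and at least 1 of the libraries compared held 50 reads.

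Itraconazole was compared with the control to describe the response to the azole alone. Ergosterol biosynthesis genes were higher in the itraconazole library, with 10 of 23 measured members at least 2-fold higher, none at least 2-fold lower and a list median of 0.88 on the log2 scale. ERG24, a sterol reductase (gene 40028243, scaffold NW_021640165.1, positions 2027367 to 2028692), was 5.13-fold higher (95% interval 4.99 to 5.29). The ratio was 3.04 for ERG1, the squalene epoxidase, 2.91 for ERG2, the sterol isomerase, 2.86 for ERG10, acetyl-CoA acetyltransferase, 2.59 for ERG6, a sterol methyltransferase, and 2.47 for ERG25, a methyl sterol oxidase. ERG3, the sterol desaturase, was 2.26-fold higher (2.19 to 2.32), and ERG11 itself (gene 40026303, scaffold NW_021640163.1, positions 208069 to 209643) was 2.06-fold higher. UPC2, the transcription factor of sterol genes, was 1.79-fold higher and so stayed under the size rule. The list median lay above those of all 10000 random lists matched on expression (percentile 100).

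**Figure D1:**
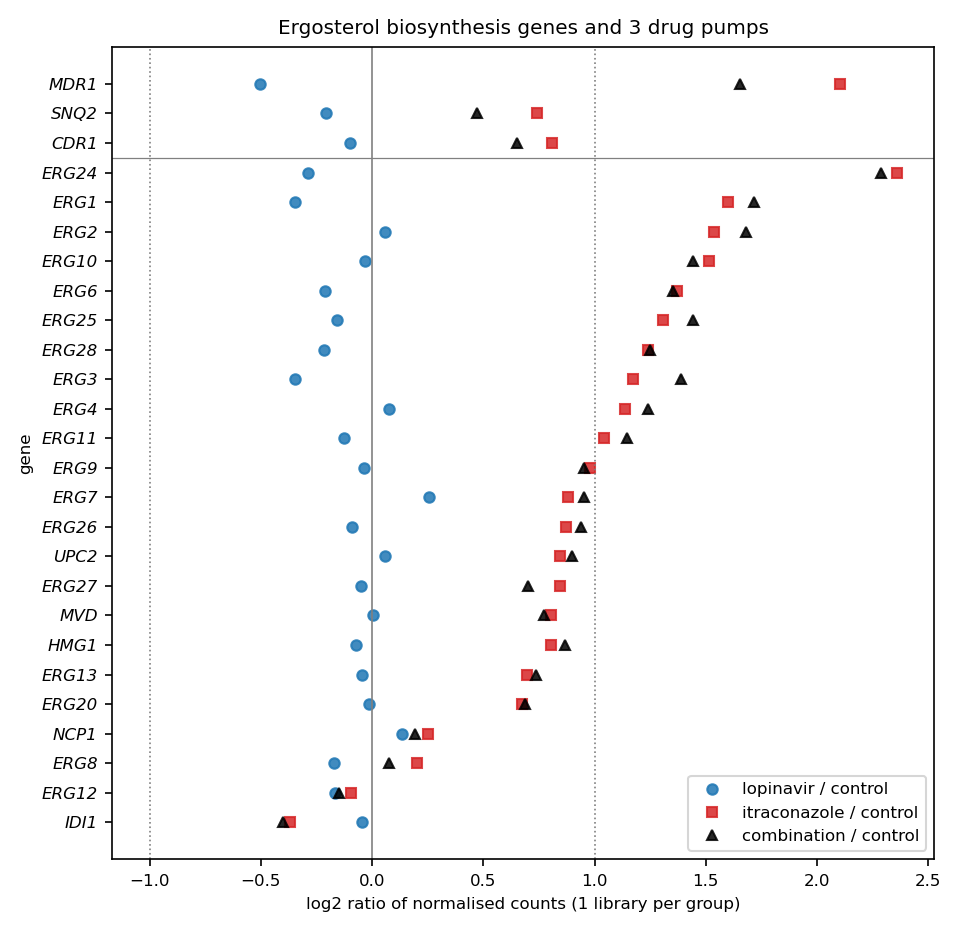
Log2 ratios of normalised counts (x axis) for the 23 measured ergosterol biosynthesis genes and for CDR1, SNQ2 and MDR1 (y axis), each drug library against the control library, 1 library per group. The dotted lines mark 2-fold; 10 ergosterol genes lie at or beyond the upper line with itraconazole and 10 with the combination, and none with lopinavir.

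Among drug pumps, MDR1, a major facilitator efflux pump (gene 40029187), was 4.31-fold higher in the itraconazole library (4.13 to 4.49) and was the single member of its 6 measured genes past 2-fold. CDR1, the ABC pump associated with azole efflux, was 1.75-fold higher (1.72 to 1.78). The 5 measured ABC genes had a median of 0.66, at percentile 99.9 of matched random lists, with none past 2-fold. The highest ratio of any named gene was that of FRE7, a metalloreductase, at 6.55 (6.01 to 7.16). RCT1 was 4.30-fold higher, PRA1, a secreted zinc-binding protein, 4.28-fold, SFH5, a phosphatidylinositol transfer protein, 2.70-fold, and PMC1, the vacuolar calcium pump, 2.36-fold. SAP9, a cell-surface aspartyl protease, was 2.14-fold higher, against 1.38-fold for YPS7 and 1.23-fold for APR1, the other measured proteases of that list. XOG1, an exoglucanase, was the single cell wall gene of 30 measured that passed the rule, at 2.00-fold.

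Cytosolic ribosomal protein genes were lower in the itraconazole library. All 64 measured members had ratios below 1, 26 of them at least 2-fold lower, and the list median was -0.91 (percentile 0). With the length trend subtracted the median was -0.78 and 6 members were at least 2-fold lower. RPL38 was 2.64-fold lower and RPS21B 2.60-fold lower, and RPL29 and RPS27, which carry ribosomal protein names outside the fixed list, were 2.97-fold and 2.73-fold lower. The median was -0.36 for ribosome biogenesis, where NIP7 was 2.09-fold lower and 48 of 49 members stayed within 2-fold (all 49 with the length trend subtracted), and -0.45 for the 10 mitochondrial ribosomal proteins (percentile 0.02), where MRPL36 was 1.71-fold lower. Histone and DNA replication genes had a median of -0.69 (percentile 0), with 4 of 25 at least 2-fold lower, or 2 with the length trend subtracted. HHF22, a histone H4 gene, was 2.45-fold lower and RNR1, a ribonucleotide reductase subunit, 2.19-fold lower, whereas the histone gene HHT1 lay at -0.01. Histone genes exist in near-identical copies, so the division of reads among them is uncertain.

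Among genes of sugar metabolism, a few were much lower with itraconazole while their lists were mixed. ADH1, an alcohol dehydrogenase (gene 40029539, scaffold NW_021640166.1, positions 570562 to 571608), was 4.94-fold lower (4.82 to 5.06) and PDC11, pyruvate decarboxylase, 3.40-fold lower (3.27 to 3.54). Of 8 measured fermentation genes, 3 were at least 2-fold lower and the list median was -0.48 (percentile 0.71). Glycolysis had a median of -0.41 (percentile 0.36), with HXK2, a hexokinase, 2.26-fold lower, the other 13 members within 2-fold and 4 of the 14 above the control. PCK1, of gluconeogenesis, was 2.55-fold lower, while that list of 8 had a median of -0.06. YHB1, a flavohaemoglobin that detoxifies nitric oxide, was 4.73-fold lower (4.61 to 4.87), SUT1, a transcription factor, 4.07-fold, and MAE1, malic enzyme, 2.58-fold. FTR2, an iron permease, was 3.19-fold lower, ZRT2, a zinc transporter, 2.87-fold and CTR1, a copper transporter, 2.18-fold. The 12 measured iron and copper genes went both ways, with 1 higher, 2 lower and a median of 0.20. SRR1, a response regulator, was 2.69-fold lower.

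Heat shock, permease and respiratory chain genes had no member past 2-fold with itraconazole. The median was -0.24 for heat shock proteins and chaperones (percentile 0.28), where HSP60 was 1.82-fold lower and HSP21 1.71-fold lower, and 0.26 for amino acid and other permeases (percentile 98.4), where AGP2 was 1.55-fold higher. Respiratory chain genes had a median of -0.22 at percentile 0.44, which became percentile 27.9 among random lists matched on gene length as well; the permeases then lay at 96.6. Medians lay inside the central 95% of random lists for hexose transport (-0.15), the tricarboxylic acid cycle (-0.14), oxidative stress defence (0.00), cell wall and adhesins (-0.02), the proteasome (0.08), amino acid biosynthesis (-0.03), sphingolipid and fatty acid synthesis (-0.01), peroxisome and beta-oxidation (0.06), zinc cluster factors (0.07) and major facilitator drug transporters (0.13). ALK2, the second measured cytochrome P450 gene beside ERG11, was 1.42-fold higher. In all, 65 of 5340 genes were at least 2-fold higher and 86 at least 2-fold lower. Simulated unchanged libraries gave at most 1 gene past the rule, with or without added library noise. That noise was set from the 2 most alike libraries, so differences between cultures were not tested. Ratios followed gene length (r = 0.19 across genes, which are not independent), and with this trend subtracted 72 genes were higher and 53 lower.

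**Figure D2:**
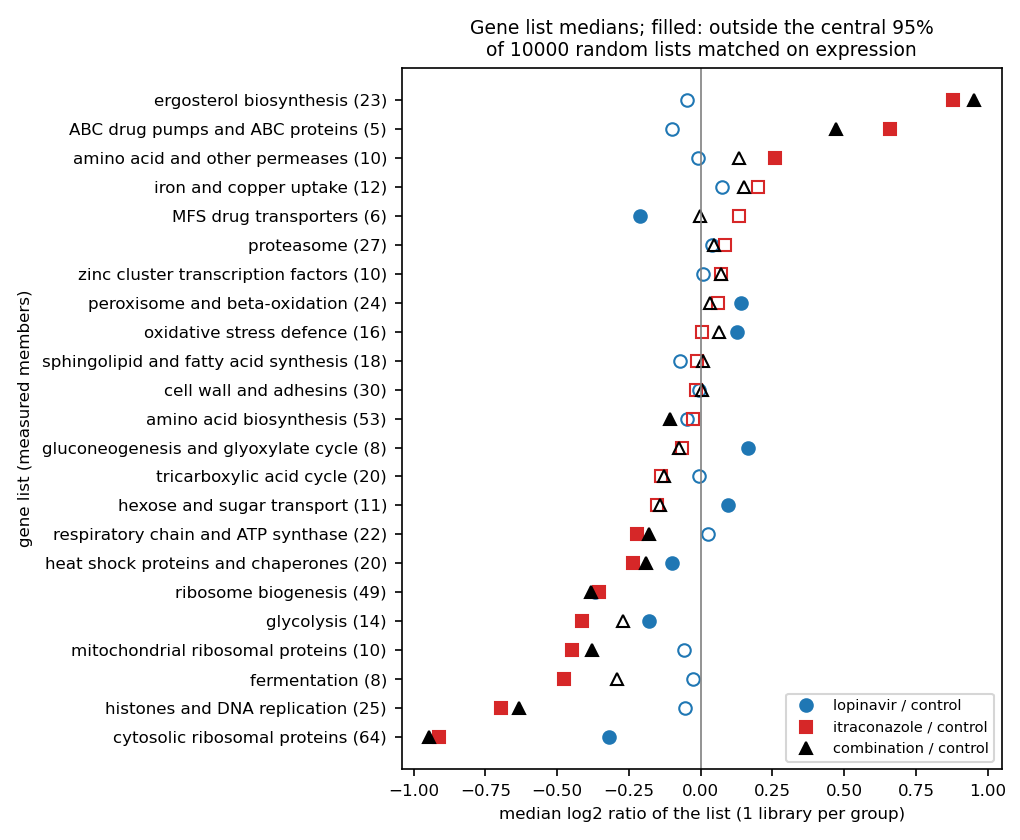
Median log2 ratio (x axis) of the 23 gene lists with at least 5 measured members (y axis, number measured in parentheses), each drug library against the control library. Filled symbols lie outside the central 95% of 10000 random lists matched on expression; ergosterol biosynthesis is highest with itraconazole at 0.88 and cytosolic ribosomal proteins lowest at -0.91.

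Lopinavir was compared with the control to describe the response to the protease inhibitor alone. Few genes were 2-fold apart, and 4 of the 11 lower ones carried a symbol: TYE7, PDC11, SHA3 and ADH1. TYE7, a transcription factor of glycolytic genes (gene 40029380, scaffold NW_021640166.1, positions 208353 to 209138), was 2.84-fold lower (2.53 to 3.18). PDC11 was 2.49-fold lower (2.40 to 2.59), SHA3, a kinase linked to glucose transport, 2.49-fold lower (2.39 to 2.59), and ADH1 2.44-fold lower (2.39 to 2.49). Under the 2-fold rule, YHB1 was 1.89-fold lower, the small heat shock gene HSP21 1.86-fold, RLP24 1.69-fold, ADH5 1.68-fold, SMF12 1.65-fold, RCL1 1.63-fold, HAP41 1.61-fold and HXK2 1.57-fold. RHR2, a glycerol phosphatase, was the single named gene past the rule in the other direction, at 2.01-fold higher (1.86 to 2.18). HMX1, haem oxygenase, was 1.80-fold higher, AGA1 1.73-fold, AFP99 1.66-fold, MET1, of sirohaem synthesis, 1.63-fold, the cell wall gene PGA45 1.58-fold, PGA25 1.51-fold, PRY1 1.49-fold, and INO1, TRY4 and NCE103, carbonic anhydrase, each 1.44-fold.

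No ergosterol gene was 2-fold apart with lopinavir, and that list's median was -0.05 (percentile 12.2). ERG3 was 1.27-fold lower, ERG11 1.09-fold lower, CDR1 1.07-fold lower and MDR1 1.42-fold lower, and UPC2 had a ratio of 1.04 with an interval that included 1. Small differences of 1 sign ran through the translation genes: 64 of 64 cytosolic ribosomal protein genes (median -0.32) and 48 of 49 ribosome biogenesis genes (median -0.37) had lower counts than in the control, none of them 2-fold, and both lists lay at percentile 0. Glycolysis (median -0.18, 13 of 14 below the control), heat shock proteins (-0.10) and major facilitator drug transporters (-0.21, 5 of 6 below) lay under the central 95% of random lists. Above it lay peroxisome and beta-oxidation (0.14, 22 of 24 above the control), gluconeogenesis and the glyoxylate cycle (0.17), oxidative stress defence (0.13, with the catalase gene CAT1 1.35-fold higher) and, at percentile 97.7, hexose transport (0.10), which lay at 95.7 among lists matched on length too. The fermentation list as a whole had a median of -0.03, with 3 of 8 members above the control. Beside PDC11, ADH1 and ADH5 it holds ADH2, which was 1.14-fold higher, and ACS1, which was 1.33-fold higher. ACS1 also belongs to the gluconeogenesis list. Amino acid biosynthesis had a median of -0.05 (percentile 2.88), which lay at percentile 1.01 among lists matched on length. Of 5324 genes, 2 were at least 2-fold higher and 11 lower; the other gene on the higher side, CJI96_0004074, had 18 reads in the control and 55 with lopinavir and is named after its values were seen.

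The combination was compared with the control to describe the joint response. The ergosterol genes were again higher, with 10 of 23 at least 2-fold higher and a median of 0.95 (percentile 100). ERG24 was 4.88-fold higher (4.74 to 5.03), ERG1 3.29-fold, ERG2 3.20-fold, ERG10 and ERG25 2.72-fold each, ERG3 2.62-fold and ERG11 2.21-fold (2.17 to 2.25), with UPC2 at 1.86-fold. RCT1 had the highest ratio of any named gene at 5.48 (5.27 to 5.71). Outside the ergosterol list it was followed by FRE7 at 4.52, PRA1 at 3.59, MDR1 at 3.15 (3.02 to 3.29), AFP99 at 2.93 and SFH5 at 2.78. CDR1 was 1.57-fold higher, SAP9 1.98-fold and XOG1 1.93-fold. The lowest named genes were FTR2 (3.61-fold lower), ZRT2 (3.59-fold), SRR1 (3.05-fold), YHB1 (2.83-fold), ADH1 (2.66-fold), SAH1, S-adenosylhomocysteine hydrolase (2.59-fold), CTR1 (2.43-fold), NIP7 (2.33-fold), CDC6, a replication licensing factor (2.29-fold), RPL30, RPS10 and PCL1, a cyclin (2.28-fold each).

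All 64 cytosolic ribosomal protein genes were below the control in the combination library, 19 at least 2-fold, with a median of -0.95 (percentile 0); with the length trend subtracted the median was -0.86 and 8 were at least 2-fold lower. Histone and replication genes had a median of -0.63 (percentile 0, 3 of 25 at least 2-fold lower), mitochondrial ribosomal proteins -0.38 and ribosome biogenesis -0.38. Glycolysis at -0.27 (percentile 3.62) and fermentation at -0.29 (percentile 6.27) lay inside the central 95% of random lists; matched on length as well, glycolysis lay at percentile 1.86. PDC11 was 2.23-fold lower and HXK2 2.05-fold lower. Amino acid biosynthesis had a median of -0.11 (percentile 1.18), with LEU1 1.78-fold lower and ILV3 1.77-fold lower. Of 5334 genes, 70 were at least 2-fold higher and 72 lower, and with the length trend subtracted 74 were higher and 52 lower.

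The combination was then set against itraconazole alone, which asks what lopinavir added in the presence of the azole. These 2 libraries differed least of all pairs compared, with 2 of 5337 genes at least 2-fold higher and 2 lower. All 4 are named after their values were seen: CJI96_0000038 had 55 reads with itraconazole and 160 with the combination, gene_40029690 (the ID of the deposited table) had 1364 and 2782, CJI96_0001938 had 73 and 21, and CSK1 had 53 and 24. Ergosterol genes did not separate the 2 libraries (median 0.01, 13 of 23 above and 10 below), and ERG11 had a ratio of 1.07 (1.06 to 1.09). Fermentation genes were higher with the combination, with 7 of 8 above itraconazole alone and a median of 0.36 (percentile 100), although none was 2-fold apart. ADH1 was 1.86-fold higher (1.81 to 1.91), ADH2 1.61-fold and PDC11 1.52-fold, and SUT1, YHB1, MAE1 and the transcription factor gene RLM1 were 1.98-fold, 1.68-fold, 1.51-fold and 1.51-fold higher. Glycolysis had a median of 0.14 (percentile 99.98, 12 of 14 above). Among pump and metal genes none was 2-fold apart; MDR1 was 1.37-fold lower (1.33 to 1.40), CDR1 1.11-fold lower, the polyamine transporter gene TPO3 1.39-fold, FRE7 1.45-fold and FRP1 1.62-fold. The medians were -0.15 for the 5 ABC genes, -0.15 for the 6 major facilitator genes and -0.11 for iron and copper uptake, with 5 of 5, 5 of 6 and 10 of 12 below itraconazole alone, all under the central 95% of random lists, though the ABC list moved to percentile 4.22 with the length trend subtracted. ENG1, an endoglucanase, was 1.40-fold lower, PHR3 1.39-fold and AMO1 1.29-fold. Ratios followed gene length here too, with the opposite sign to itraconazole against the control (r = -0.25 across genes, which are not independent). The ribosomal protein median was -0.01 at percentile 33.8, but -0.08 and percentile 0 with the length trend subtracted.

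Set against lopinavir alone, which asks what itraconazole added in the presence of lopinavir, the combination showed the sterol genes again. Of 23 ergosterol genes, 11 were at least 2-fold higher (median 0.99, percentile 100), with ERG24 at 5.96-fold (5.78 to 6.15), ERG1 at 4.18-fold, ERG3 at 3.33-fold, ERG2 at 3.08-fold, ERG25 at 3.03-fold, ERG6 at 2.96-fold and ERG11 at 2.42-fold (2.38 to 2.46). MDR1 was 4.47-fold higher, RCT1 and FRE7 4.25-fold each, PRA1 3.38-fold, SFH5 2.90-fold and SAP9 2.14-fold. The lowest named genes were FTR2 (2.86-fold lower), ZRT2 (2.65-fold), LTE1, of mitotic exit (2.62-fold), TOS4 (2.58-fold), SAH1 (2.48-fold), HHF22 (2.45-fold), HHT2 (2.28-fold), OPI3, a phospholipid methyltransferase (2.28-fold), KIP3, a kinesin (2.21-fold), PGA58 (2.20-fold), SAM2, S-adenosylmethionine synthetase (2.11-fold) and the histone gene HTA2 (2.08-fold). All 64 ribosomal protein genes were below lopinavir alone, none of them 2-fold, with a median of -0.64 (percentile 0). Gluconeogenesis (-0.29) and peroxisome genes (-0.08) lay inside the central 95% of random lists, but at percentiles 1.14 and 2.04 among lists matched on length. Of 5335 genes, 63 were at least 2-fold higher and 29 lower.

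**Figure D3:**
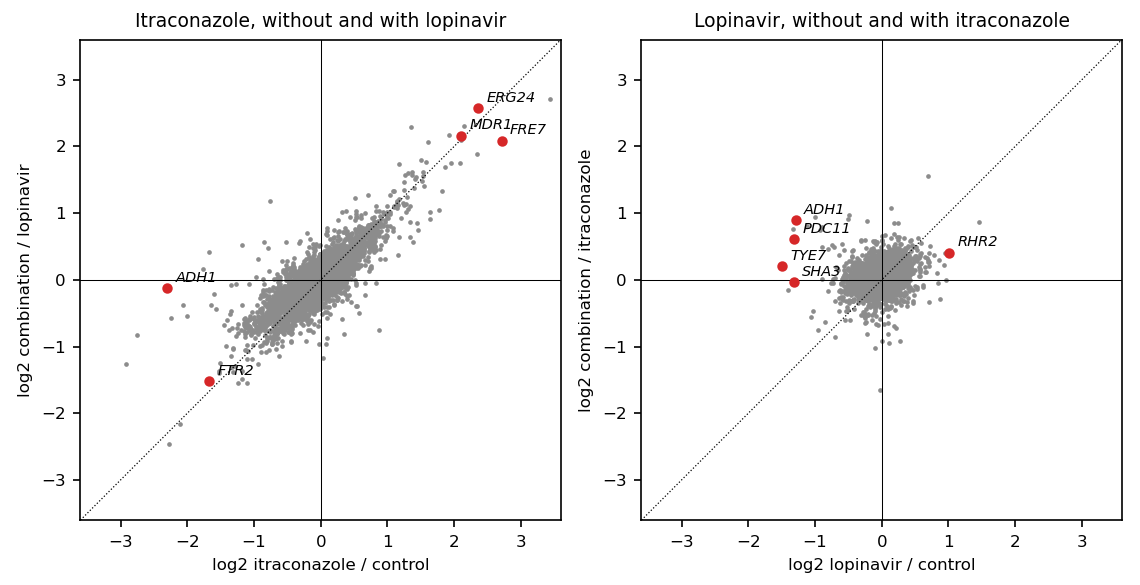
Log2 ratio of each gene for 1 drug given alone (x axes) and given on top of the other drug (y axes), for the 5346 genes with at least 50 reads in at least 1 library; the 2 ratios on each plot share no library and the dotted line marks equal values. The itraconazole ratios follow the line (r = 0.83 across genes), while the lopinavir ratios form a round cloud (r = 0.18), with ADH1 at -1.29 alone and 0.89 on top of itraconazole.

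The response to itraconazole was alike in direction with and without lopinavir. Of the 151 genes past the rule for itraconazole against the control, 148 had the same sign in the combination against lopinavir alone, and 72 were also past the rule in that direction. These 2 comparisons share no library. Over the wider set of 5346 genes with 50 reads in any library, 51 were higher and 22 lower in both, against 0.778 and 0.467 for independent lists. Of the 13 genes past the rule for lopinavir against the control, 6 had the same sign in the combination against itraconazole and none passed the rule there. Itraconazole and the combination, both against the same control library, shared 53 higher genes, against 0.851 for independent lists, and 50 lower genes, against 1.17. Their ratios correlated across genes at r = 0.92, where simulated unchanged libraries against a common control gave 0.54, and their covariance was 0.156 against a simulated 0.0109 with library noise added. Lopinavir and itraconazole shared 6 lower genes and no higher gene, against 0.177 and 0.0243 for independent lists; their r was 0.38 against a simulated 0.52, and their covariance 0.0313 against 0.0109. Lopinavir and the combination shared 7 lower genes and 1 higher gene, against 0.150 and 0.0262, with an r of 0.46 against a simulated 0.52 and a covariance of 0.0374 against 0.0109. Part of the excess in the comparisons with the control may come from that 1 library, which cannot be divided. For the 2 pairs with lopinavir, that library may account for the whole excess, and their r, under the simulated values, does not decide this. The simulated ratios had like spreads. In the data the scaled median absolute deviation was 0.153 for lopinavir, 0.323 for itraconazole and 0.324 for the combination. Such unequal spreads lower r whatever the control contributes.

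The combination was last compared with the sum of the single-drug log2 ratios. ADH1, PDC11, TYE7 and YHB1 were lower than the control with each drug alone and higher with both drugs than with itraconazole alone, and they lay above this sum. ADH1 lay 2.18 log2 units above the sum, PDC11 1.92, TYE7 1.71, YHB1 1.66, SUT1 1.46, SHA3 1.28, ADH5 1.27, RPL29 1.13 and OSM1, a fumarate reductase, 1.01. The normalised CPM of ADH1 was 1716 in the control, 704 with lopinavir, 347 with itraconazole and 645 with the combination. In all 21 of 5346 genes lay at least 1 log2 unit above the sum, and 18 of these were below the control in all 3 drug libraries. Departures followed gene length (r = -0.22 across genes, which are not independent). The lists above the central 95% of random lists were glycolysis (median 0.39), fermentation (0.36), cytosolic ribosomal proteins (0.31, all 64 above 0, or 0.24 and 59 above 0 with the length trend subtracted), ribosome biogenesis (0.30), heat shock proteins (0.12) and histones and replication (0.12). Those under it were gluconeogenesis (-0.18), iron and copper uptake (-0.14), peroxisome and beta-oxidation (-0.12), hexose transport (-0.12) and oxidative stress defence (-0.10); hexose transport lay at percentile 4.76 among lists matched on length too, and iron and copper uptake at percentile 6.54 with the length trend subtracted. The proteasome (-0.06, percentile 9.73) lay under the central 95% with length handled either way, at percentile 2.01 among lists matched on length and 0.32 with the trend subtracted. The departure also equals the log2 ratio of the combination to itraconazole minus that of lopinavir to the control. For ribosomal proteins, ribosome biogenesis and heat shock proteins the first ratio had a median of -0.01 each. Their departures thus largely repeat the lopinavir medians of -0.32, -0.37 and -0.10 with the sign reversed, and are not separate evidence. The same held for peroxisome genes (-0.004, lopinavir 0.14) and gluconeogenesis (0.03, lopinavir 0.17). Ergosterol genes had a median of 0.08 (percentile 97.4, or 97.8 among lists matched on length and 81.2 with the trend subtracted), with ERG3 at 0.56, ERG11 at 0.23, MDR1 at 0.05 and CDR1 at -0.05. HMX1 at -0.90 and FRP1 at -0.88 were the lowest named genes. HMX1 had 324 CPM with itraconazole and 313 with the combination, so its departure largely repeats its lopinavir log2 ratio of 0.84 with the sign reversed. The 5 genes at least 1 log2 unit below the sum carried no name; they are given after their values were seen as CJI96_0001938 (-1.63), CJI96_0004895 (-1.16), CJI96_0005133 (-1.04) and, by the IDs of the deposited table, gene_40028399 (-1.20) and gene_40026449 (-1.06), and all but CJI96_0004895 had under 100 reads in each library.

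**Figure D4:**
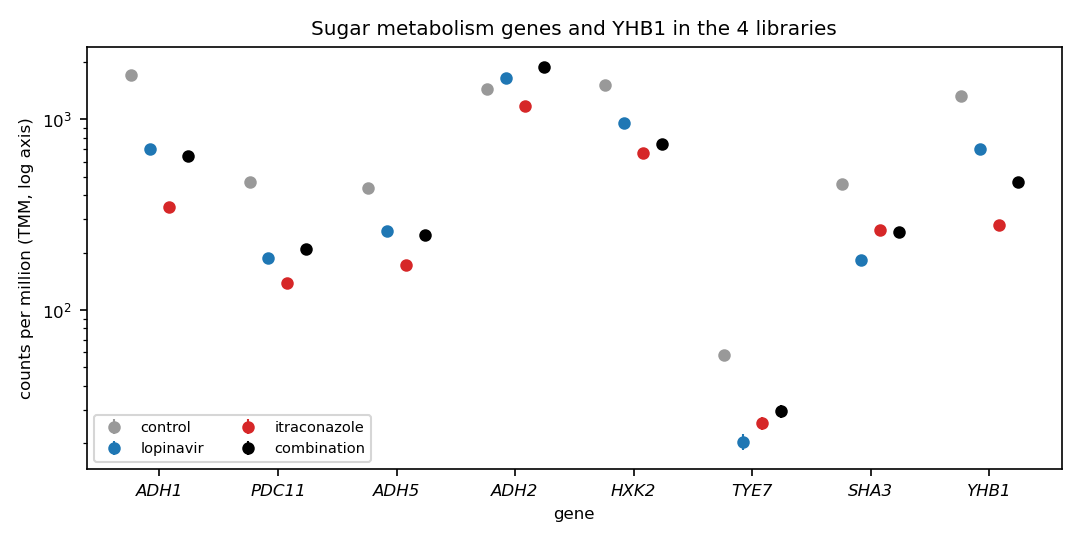
CPM after TMM normalisation (y axis, log scale) of 8 genes (x axis) in the 4 libraries, with 95% Poisson intervals of counting error, mostly smaller than the symbols. ADH1, PDC11, ADH5, HXK2, TYE7, SHA3 and YHB1 lie below the control in all 3 drug libraries, and ADH1 is lowest with itraconazole at 347.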

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

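The tests of the control library, of counting noise gene by gene, of the shared lopinavir effect, of high-count genes, of abundant genes and of cultures were chosen after the results were seen. For 8 named genes the lopinavir ratio pointed in opposite directions without and with itraconazole, with both 95% counting intervals off 1 and a gap of at least 1 log2 unit; each rests on 1 library per group and the difference was not tested. The log2 ratio was -1.29 without and 0.89 with itraconazole for ADH1 (a gap of 2.18), -1.32 and 0.61 for PDC11 (1.92), a 2.84-fold lower count without and 0.21 with for TYE7 (1.71), -0.92 and 0.74 for YHB1 (1.66), -0.48 and 0.97 for SUT1 (1.46), -0.75 and 0.53 for ADH5 (1.27), -0.60 and 0.53 for RPL29 (1.13) and -0.56 and 0.45 for OSM1 (1.01).

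The 21 genes above the sum of the single-drug ratios might reflect a control library that stood apart by itself. Their median log2 ratio of the combination to itraconazole, neither of which is the control, was 0.529; when this ratio was shuffled among genes of like expression and genes were picked by the same rule, the median was 0.213, the highest of 1000 shuffles was 0.757, 18 shuffles reached the observed value, and 18 genes were picked on median and 27 at most. The selection thus accounts for part of the value, and a control library apart stays open as the whole cause. Counting noise gave a mean of 1.97 genes and at most 6 in 100 simulated additive sets. Of the 21 genes, 17 were also over 5 counting standard errors above the sum, against 0 in every simulated set under the same rule. A normal tail over all tested genes, without the size rule, would give 0.00153. This speaks against counting noise for these 17 and says nothing about differences between cultures. A joint response to the 2 drugs was not tested. The fermentation list as a whole did not stand apart with lopinavir alone (median -0.03, at percentile 39.0 of random lists), but its members were mixed. PDC11 (-1.32), ADH1 (-1.29) and ADH5 (-0.75) were lower, and ACS1 (0.41) and ADH2 (0.18) were higher. In all, 5 of 8 members lay below the control and 3 above.

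The lower ribosomal protein counts with itraconazole might come from the short length of these genes, since ratios followed length. Among random lists matched on length and expression and drawn outside the list, whose median was -0.13, the list's -0.91 lay at percentile 0, and with the length trend subtracted its median was -0.78, although members at least 2-fold lower went from 26 to 6. Length may thus account for part of the size, but not for the whole difference. How large this part is stays open, because the trend was fitted on all tested genes, these among them. Genes outside the 20 with the highest summed counts held 88.5% of the counts in the control and 88.6% with itraconazole. These 20 were not the same set as the 20 most abundant genes used elsewhere, which were ranked by mean share. The log2 ratio of 0.00135 shows no shift of counts to a few genes. Such a shift would lower all other genes alike, and so could not by itself set this list apart from matched lists. Slower growth of the treated cultures is a biological candidate that growth data, absent here, would be needed to test.

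The lopinavir ratios without and with itraconazole correlated at r = 0.18 across genes, which are not independent, and this low value might come from counting noise. In 100 simulations of 1 shared lopinavir effect the lowest correlation was 0.772 and the highest 0.818, and among 2419 genes with a mean of at least 2000 reads the observed value was 0.159. With the length trend subtracted from both ratios it was 0.207. A lopinavir response that depends on itraconazole and plain differences between cultures predict the same low value, and with 1 library per group the data do not separate them.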

How the results depend on the processing

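Of 180 counts of genes and overlaps under alternatives, 148 stayed within 1.5 times the reported count and 32 moved further. Of values for single genes and lists, 5010 stayed the same and 175 moved. Size factors from DESeq2, library totals and a prior of 0.5 moved no count this far, nor did removal of the 20 most abundant genes, which hardly altered the scaling and so tests little. The cause of a move was not tested, except that the 3-fold rule and the minimum of 200 reads shorten lists by construction and no minimum lengthens them. Under the 3-fold rule the counts higher and lower were 0 and 0 for lopinavir, 16 and 13 for itraconazole, 22 and 8 for the combination, 0 and 1 for the combination against itraconazole, 19 and 2 against lopinavir, and 9 above and 1 below additivity. Shared genes were then 0 lower for lopinavir and itraconazole, 13 higher and 4 lower for itraconazole and the combination, and 0 higher and 0 lower for lopinavir and the combination. With no minimum they were 31 higher and 36 lower for lopinavir, 28 and 20 for the combination against itraconazole, 61 lower against lopinavir, and 65 above and 48 below additivity. With 200 reads they were 1 higher for lopinavir, 1 higher and 0 lower for the combination against itraconazole, and 1 below additivity. A prior of 10 left 1 lower for the combination against itraconazole and 2 below additivity, thinning left 3 below additivity, and the length trend left 53 lower with itraconazole. No paired analysis was possible because each group held 1 library, all numbered 1. Not run were the GC trend (no genome), DESeq2 as a test, leave-one-out, the replicate block, and list matching without signatures (none could be used).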

Other observations

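These genes were chosen after their values were seen. Neighbouring genes on the scaffolds shared a direction with itraconazole in a few places. Neighbours were consecutive among genes with at least 50 reads in any library, so genes with fewer reads may lie between them. The urea genes DUR3, a transporter, and DUR1,2, urea amidolyase, are such neighbours. Both were higher in the itraconazole library, at log2 ratios of 1.08 and 1.08, and in the combination library, at 0.97 and 0.99. The 65 genes at least 2-fold higher with itraconazole formed 6 adjacent pairs, against a mean of 0.768 and a maximum of 5 in 10000 random placements; the 86 lower genes formed 6, against a mean of 1.35 and a maximum of 7. The higher pairs also included gene_40029690 with gene_40029691, which carry no locus tag. The lower pairs included HHT2 with HHF22, RPS22A with RPS14B, and CJI96_0005034 with CJI96_0005035. The unnamed genes CJI96_0005034 and CJI96_0005035 had 14286 and 23633 reads in the control and 2216 and 4129 with itraconazole, and lay at -1.47 and -1.12 with lopinavir. CJI96_0002267 had 203 reads in the control, 2620 with itraconazole and 1612 with the combination.

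Values for 7 more single genes are given for itraconazole without and with lopinavir. SAH1, which removes the product of methylation, had log2 ratios of -1.33 without and -1.31 with lopinavir, SAM2, which makes the methyl donor, -0.82 and -1.08, and OPI3, which uses that donor for phospholipids, -1.03 and -1.19. The zinc transporter ZRT2 lay at -1.52 and -1.40 and the copper transporter CTR1 at -1.12 and -1.05, whereas PRA1, the zinc-binding protein, lay at 2.09 and 1.76 and the metalloreductase FRE7 at 2.71 and 2.08.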
